A study of Mus musculus with 8 samples.

How the data were processed

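Total RNA from belly skin of 4 hurpin-transgenic and 3 wildtype mice aged 8 months had been labelled by the authors with the Affymetrix one-cycle protocol and hybridised to mouse expression arrays, 1 animal per array, with wildtype female 29 on 2 arrays. The deposited values are signal intensity on a linear scale, made by the authors with MAS5 (the version is not given) and scaled so that each array has the same mean after leaving out the lowest and highest 2% of values, which was 500.003 on each of the 8 arrays. Detection calls were not part of the deposited table. The table held 45101 probe sets, of which 64 were array controls and 45037 were not. Gene symbols came from the array annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and probe sets with several or no symbols were not named by gene. Gene order was taken from RefSeq on assembly GRCm38.p6.

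Values were analysed as log2 of intensity plus 21.8, the 20th percentile of all values, without further normalization between arrays. The arrays of wildtype 29 were averaged on the log2 scale, which gave 7 animals. Probe sets with a mean log2 below the 40th percentile (6.45) over the 7 animals were left out, which left 27022 probe sets for 13559 gene symbols. Transgenic and wildtype animals were compared with limma 3.58.1 in R 4.3.3 (linear model with group only, empirical Bayes with a trend, 2-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The interaction of group and sex was tested in the same way with group, sex and their product. Differences are transgenic minus wildtype on the log2 scale.

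The 30 gene lists for skin cell types and pathways, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. Lists with 5 or more measured members were tested with limma camera at a preset correlation of 0.01, with the most abundant probe set per gene and all 13559 genes as background, and again with an estimated correlation and with fry. For each list the number of members passing when adjusted over the list alone was also counted. Named genes were those called with no overlap between groups, filled up to 10 in each direction with the largest log2 differences among probe sets with no overlap and an unadjusted p under 0.01, a set of 12 genes fixed beforehand, up to 4 members with the smallest p of each list, and sex-linked genes as a check of the labels. Where a fixed or list gene had several probe sets the most abundant is given. A probe set with no symbol falls outside this rule and is described because it is among the 4 called.

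The ratio of 3' to 5' signal was taken from control probe sets of Gapdh and of 4 Bacillus spike-ins and compared between groups with an exact permutation test. That of Actb was taken without a test. The 7 animals can be split 4 against 3 in 35 ways, so an exact 2-sided p cannot go below 0.0571. The pipeline was tested on simulated data with the measured variances, in which 200 of 27022 probe sets were shifted: 12.5% were recovered at a log2 shift of 1, 81% at 2 and 93% at 3, with 1, 5 and 14 false calls, and with no shift limma called 0. A simulated interaction of 3 was recovered for 35.5%. A mast cell list shifted by 1 was called, with 0 other lists. The simulated noise was drawn independently for each probe set, so it cannot show how the list test behaves where members are correlated. Nor can it show how many false calls limma makes where many probe sets vary together across animals. In the measured data the estimated correlation was 0.511 for mast cell and 0.469 for skeletal muscle genes.

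Alternatives covered quantile and cyclic loess normalization, a pseudocount of 5.45 or 87.2 in place of 21.8, no level filter and a filter at the 60th percentile, empirical Bayes without trend or robust, sex as a covariate, the first, the second or both arrays of wildtype 29 as separate samples, other thresholds, 1 probe set per gene, a test with no variance shared between probe sets, and each animal left out in turn. Fits without transgenic 7 and 84 together, with the log2 Gapdh ratio as a covariate and with the hair keratin mean as a covariate were added after seeing the data. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.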

Results

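Gene expression was measured in belly skin of 8-month-old mice by oligonucleotide array. The transgenic mice carried a transgene for human hurpin, also called SERPINB13, a clade B serpin that inhibits the cysteine protease cathepsin L. The transgenic group held 4 animals (females 7 and 84, males 11 and 17), and the wildtype group held 3 (males 26 and 28, female 29). Wildtype female 29 was measured on 2 arrays, which made 8 arrays in all. Summed signal intensity per array lay between 34785081 and 37857733, and the number of arrays limited the precision of every comparison.

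Arrays of the groups differed in how far the labelled targets reached towards the 5' end of the transcripts. The ratio of 3' to 5' signal of Gapdh, a glycolytic enzyme used as an array control, was 13.8 in transgenic 7, 17.2 in transgenic 84, 4.68 in transgenic 17 and 1.45 in transgenic 11. It lay between 0.927 and 1.41 on the 4 wildtype arrays. On the log2 scale the mean was 2.67 ± 1.64 (SD, n = 4) in transgenic and 0.15 ± 0.09 (SD, n = 3) in wildtype animals (exact permutation test, 2-sided p = 0.0571, the smallest that 4 against 3 animals can give). Bacillus spike-in transcripts moved the same way, with log2 means of 2.32 ± 0.59 against 1.18 ± 0.09 (exact permutation p = 0.0571). The ratio of Actb, another array control, was 4.33 in transgenic 7, 5.88 in transgenic 84 and 3.33 in transgenic 17. In transgenic 11 it was 2.40, within the range of 2.21 to 2.64 on the wildtype arrays. The hybridisation controls gave log2 signals of 12.39 ± 0.32 and 12.29 ± 0.16 (exact permutation p = 0.686).

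**Figure D1:**
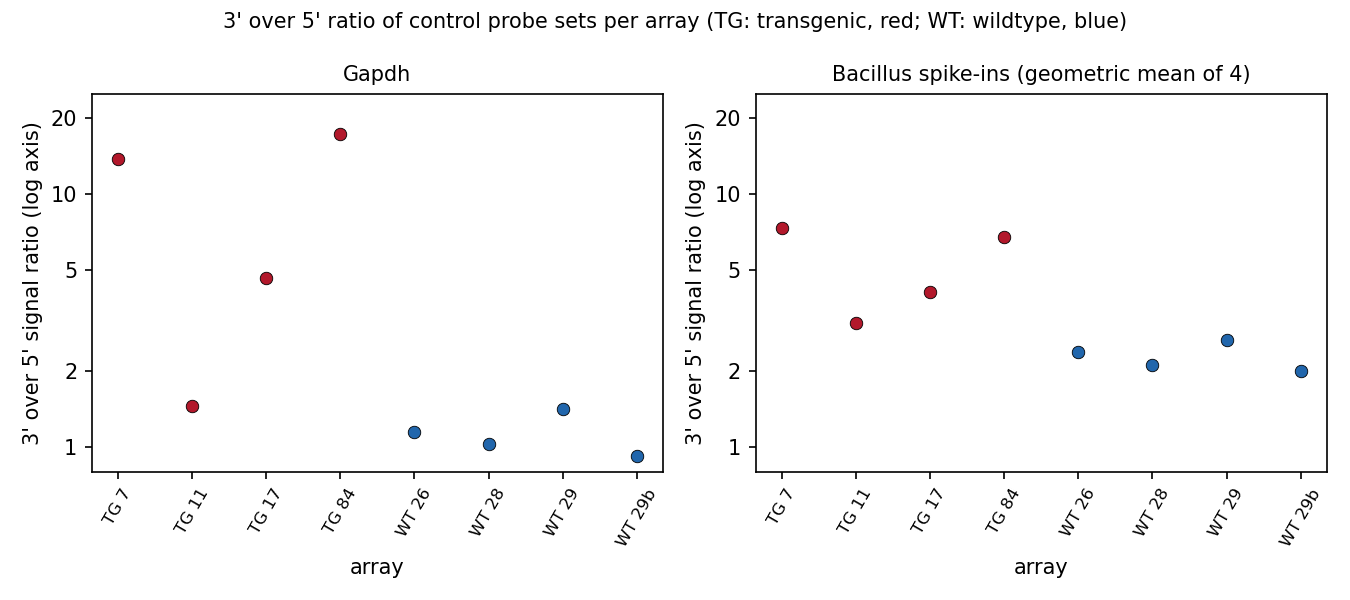
Ratio of 3' to 5' signal on each of the 8 arrays (log axis, no unit), for Gapdh and for the geometric mean of 4 Bacillus spike-ins; each point is an array. For Gapdh, transgenic 7 and 84 stood at 13.8 and 17.2, transgenic 17 at 4.68, and transgenic 11 at 1.45, close to wildtype 29 at 1.41.

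The comparison of transgenic with wildtype skin asked which transcripts differ in mice that carry the transgene of the cathepsin L inhibitor. Khdrbs1, an RNA-binding protein that takes part in splicing and signalling, rose by 2.31 on the log2 scale (SE 0.181), from 8.92 ± 0.08 in wildtype (SD, n = 3) to 11.22 ± 0.29 in transgenic skin (SD, n = 4; limma adjusted p = 0.00806). A probe set that carries no gene symbol rose by 3.54 (SE 0.256), from 4.92 ± 0.19 to 8.46 ± 0.30 (adjusted p = 0.00797). Its wildtype values lay near the floor of the scale (4.45, the log2 of the pseudocount), so the size depended on the pseudocount, with 4.62 at 5.45 and 2.13 at 87.2. Rbm39, a splicing factor, fell by 2.28 on the log2 scale (SE 0.197), from 9.52 ± 0.30 to 7.25 ± 0.14 (adjusted p = 0.0121). Gna13, the alpha subunit of a heterotrimeric G protein that signals to the cytoskeleton, fell by 1.85 (SE 0.196), from 10.63 ± 0.12 to 8.78 ± 0.31 (adjusted p = 0.0482).

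These were the 4 probe sets called among 27022 tested, 2 higher and 2 lower, and in each of them all 4 transgenic animals lay on the same side of all 3 wildtype animals. The other probe sets of the 3 genes did not share the shift evenly, and each gene had a probe set that went the other way. With the most abundant probe set per gene, limma called 0 genes. The log2 difference ranged from -1.93 to 1.03 over the other 11 probe sets of Rbm39, from -0.54 to 0.71 for those of Khdrbs1 and from -1.78 to 0.23 for those of Gna13. At an unadjusted p under 0.05 limma gave 3161 probe sets, 1018 higher and 2143 lower, where 1351 would be expected with no difference. Groups did not overlap in 3049 probe sets (11.3%, where chance gives 5.71% on average), of which 1237 were higher and 1812 lower in transgenic skin. Neither count was compared with other splits of the animals, so how far such counts vary with no group difference was not tested. Of the 4, Gna13 was no longer called without transgenic 7, transgenic 17, wildtype 26, wildtype 28 or wildtype 29 (adjusted p from 0.0546 to 0.359), and Rbm39 without transgenic 7 (0.0566), wildtype 26 (0.0596) or wildtype 28 (0.154). The number called was 280 without transgenic 11 (260 of them lower), 12 without transgenic 17, 11 without transgenic 84, 2 without wildtype 26, and 0 without wildtype 28, where limma gave 1652 at an unadjusted p under 0.05. It was also 0 with the Gapdh 3' to 5' ratio as a covariate (851 at an unadjusted p under 0.05), which left log2 differences of 1.92 for Khdrbs1, -2.25 for Rbm39, -1.40 for Gna13 and 3.49 for the probe set without a symbol, and 0 by a test with no variance shared between probe sets (2454 at an unadjusted p under 0.05).

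**Figure D2:**
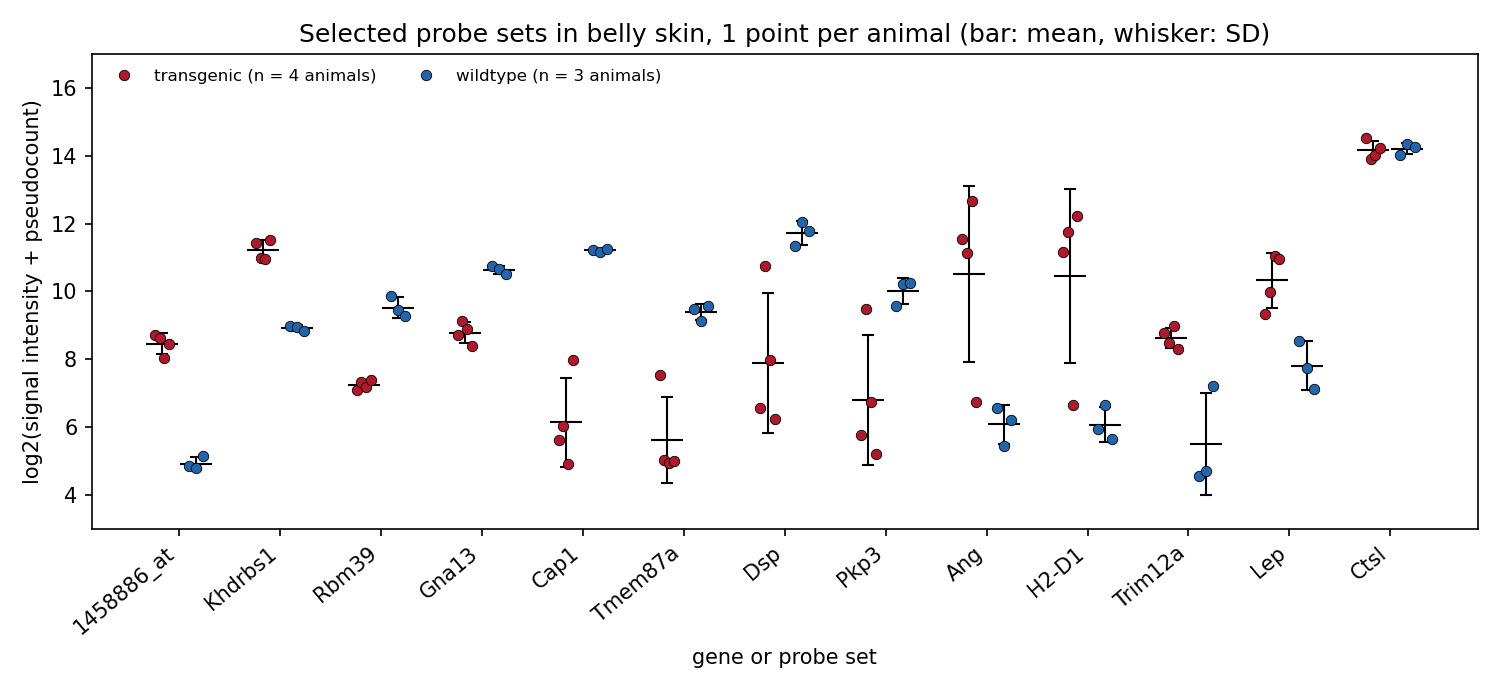
Log2 of signal intensity plus pseudocount for selected probe sets; each point is an animal (transgenic red, n = 4; wildtype blue, n = 3), bars are means and whiskers are SDs. For the probe set without a symbol, Khdrbs1, Rbm39 and Gna13 the groups are apart, with means of 8.46 against 4.92, 11.22 against 8.92, 7.25 against 9.52 and 8.78 against 10.63, while Ctsl stands at 14.16 and 14.21.

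Among probe sets that did not pass the adjusted threshold but had no overlap between groups and an unadjusted p under 0.01, the higher ones named by the selection rule held the genes of antigen presentation H2-D1 and H2-K1. H2-D1 and H2-K1 encode heavy chains of MHC class I. H2-D1 measured 10.45 ± 2.57 in transgenic and 6.07 ± 0.52 in wildtype skin, and H2-K1 measured 13.47 ± 0.84 and 11.27 ± 0.53 (SD, n = 4 and 3). Other probe sets of H2-D1 went from -1.68 to 2.97 in log2 difference. Transgenic 17 stood at 6.66 in H2-D1 itself, against 11.16 to 12.22 in the other transgenic animals. In H2-K1 it was again the lowest transgenic animal, at 12.27 against 13.67 to 14.21. Trim12a, Trim30d and Trim34a, members of a tripartite motif family with antiviral roles, had log2 differences of 3.14, 2.20 and 2.17. Their other probe sets, all below the level filter, gave 0.23, 0.79 and -0.61. Wildtype 29 stood at 7.22 for Trim12a, against 4.56 and 4.71 in the other wildtype animals, near the floor of 4.45, and the difference was 4.18 with a pseudocount of 5.45 and 1.95 with 87.2. Ang, the secreted ribonuclease angiogenin, had a log2 difference of 4.43 with transgenic 84 at 6.73 and the other transgenic animals between 11.12 and 12.67. Its other probe sets gave 2.02 and 0.51. Rpgrip1, a ciliary protein, and Snx6, a sorting nexin of endosomes, had log2 differences of 3.19 and 3.05, and the other probe sets of Snx6 ran from -0.53 to 0.37. Those of Rpgrip1, all below the level filter, gave 0.05, -0.17 and 0.02. Snx6 stood at 4.57, 7.28 and 4.67 in wildtype, and its difference was 4.09 with a pseudocount of 5.45, 1.88 with 87.2 and 2.58 to 3.94 with an animal left out. Lep, the adipocyte hormone leptin, measured 10.33 ± 0.82 in transgenic and 7.81 ± 0.71 in wildtype skin (log2 difference 2.52, SE 0.467). The limma adjusted p over these 9 genes ranged from 0.193 for Trim30d to 0.301 for Ang and H2-D1. Some passed with an animal left out: H2-D1 and H2-K1 without transgenic 17 (adjusted p = 0.00621 and 0.0391), Ang and Rpgrip1 without transgenic 84 (0.0124 for each), Trim34a without transgenic 11 (0.0429) and Trim12a without wildtype 29 (0.0185). Lep passed with the hair keratin mean as a covariate (0.0487).

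The lower genes under the same rule were 8, 6 of which had lower levels in transgenic animals with a higher Gapdh 3' to 5' ratio than in transgenic 11. Dsp, the desmosomal linker desmoplakin, had a log2 difference of -3.83 and Pkp3, a desmosomal plakophilin, one of -3.21. Emp2, an epithelial membrane protein, stood at -3.16, Ptprf, a receptor tyrosine phosphatase, at -3.001, Sdc1, a heparan sulfate proteoglycan, at -2.97, and Mbnl2, a splicing regulator, at -2.86. For these 6 genes the limma adjusted p was between 0.277 and 0.302, and all 6 passed without transgenic 11 (adjusted p from 0.0193 to 0.0369). In each of them transgenic 11, with the lowest Gapdh 3' to 5' ratio of the transgenic animals, stood highest and transgenic 17 next, while transgenic 84, with the highest ratio, stood below transgenic 7 in Dsp, Pkp3 and Emp2 but above it in Ptprf, Sdc1 and Mbnl2. Dsp measured 10.76 in transgenic 11, whose ratio was 1.45, but 6.56 and 6.25 in transgenic 7 and 84, whose ratios were 13.8 and 17.2, against 11.33 to 12.04 in wildtype. With the ratio as a covariate the log2 difference was -0.69 for Dsp, -0.34 for Pkp3, -0.29 for Emp2, -0.35 for Ptprf, -0.86 for Sdc1 and -0.90 for Mbnl2. Other probe sets gave 0.17 and 0.04 for Dsp, -0.40 for Pkp3, 0.13 and -0.10 for Ptprf and -0.16 to 0.09 for Sdc1. Those of Emp2 gave -1.12 and -0.11, and those of Mbnl2 ran from -1.18 to 0.31.

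Cap1 and Tmem87a were low in each transgenic animal, transgenic 11 included. Cap1, a regulator of actin turnover, measured 6.13 ± 1.31 in transgenic and 11.21 ± 0.05 in wildtype skin (log2 difference -5.07, SE 0.604, adjusted p = 0.0596). Its other probe set gave -4.15. Cap1 passed the threshold in 8 of its 23 alternative settings, with an adjusted p over all of them from 0.00118 to 0.79. Tmem87a measured 5.63 ± 1.27 in transgenic and 9.39 ± 0.23 in wildtype skin (adjusted p = 0.153). It passed in 3 of its 23 alternative settings, without transgenic 7 (adjusted p = 0.00294), without transgenic 7 and 84 (0.0137) and with 8 arrays as separate samples (0.038), with a range from 0.00294 to 1. With the Gapdh ratio as a covariate the log2 differences were -5.96 for Cap1 and -4.64 for Tmem87a. Transgenic values of both reached down near the floor of 4.45 (4.91 for Cap1 in transgenic 17, and 4.95 to 5.04 for Tmem87a in transgenic 11, 17 and 84), so the sizes depended on the pseudocount. With 5.45 and 87.2 they were -5.62 and -4.06 for Cap1 and -4.54 and -2.58 for Tmem87a.

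Ctsl, the protease that hurpin inhibits, measured 14.16 ± 0.27 in transgenic and 14.21 ± 0.17 in wildtype skin (SD, n = 4 and 3). Its log2 difference was -0.05, with a 95% confidence interval from -0.42 to 0.32, and the sign turned without transgenic 11 (0.04) and without wildtype 28 (0.015). Over all alternatives the difference of this probe set of Ctsl ran from -0.39 to 0.04. Its other probe set, below the level filter, gave 0.66. Ctsb, a related lysosomal protease, gave 0.08 from its most abundant probe set, with -0.02 without wildtype 26 and -0.07 after cyclic loess normalization, and -0.78 from another. Ctsd, an aspartic protease, gave -0.66 (adjusted p = 0.353), Ctsf -1.01 and Ctsa -0.61 (its other probe set 0.65). Ctsd moved to 0.01 with the Gapdh ratio as a covariate, and Ctsf to -0.41. The list of cathepsins and their cystatin inhibitors had a median log2 difference of -0.08 over 19 genes, 12 of them below 0 (adjusted p = 0.241). Its adjusted p was 0.0223 after quantile and 0.00735 after cyclic loess normalization, with medians of -0.13 and -0.19, and 0.0327 without wildtype 29, all with the preset correlation (adjusted p = 0.988 with an estimated correlation over all 7 animals). No probe set was annotated to Serpinb13, alone or with other genes, so neither its mouse transcript nor the human transgene could be read from the annotated probe sets. The list of clade B serpins had a median of 0.05 over 13 genes (adjusted p = 0.971).

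Epidermal genes gave no call in the comparison of all 7 animals, and their lists were called lower in some alternatives. Krt10, Lor and Flg, products of differentiating keratinocytes, had log2 differences of 0.19, 0.30 and 0.16. Ivl gave -0.39 and Casp14, the caspase of cornification, -0.54 (its other probe set 0.30). Krt6a and Krt16, keratins of stressed epidermis, gave -0.42 and -0.31, and the other probe sets of Krt6a gave -1.23 and -1.50. Cdsn, a protein of corneodesmosomes, measured 12.79 ± 0.45 in transgenic and 13.62 ± 0.07 in wildtype skin (log2 difference -0.83), and Asprv1, Tgm1 and Ppl gave -0.69, -1.22 and -0.40. None of these passed the test over all genes. The cornified envelope list of 60 genes had a median of 0.02 and a mean of -0.09 (direction of the test down, adjusted p = 0.263). Its adjusted p was 0.0293 after quantile and 0.00951 after cyclic loess normalization, where its medians were -0.01 and -0.04, and 0.0205 with the Gapdh ratio as a covariate (median -0.05), all with the preset correlation (adjusted p = 0.988 with an estimated correlation over all 7 animals). Keratinocyte stress and hyperproliferation genes had a median of 0.01 (29 genes, test direction down, adjusted p = 0.929). Basal keratinocyte genes had a median of 0.01 and a mean of -0.11 (20 genes, test direction down, adjusted p = 0.624), with Bcam at -1.25 (adjusted p = 0.301, and 0.0398 without transgenic 11). The basal list was called lower with the Gapdh ratio as a covariate (median -0.14, adjusted p = 0.00569) and with the mean over the probe sets of a gene (-0.10, 0.0462). Itga6, an integrin subunit of hemidesmosomes, gave 0.43 from its most abundant probe set and -1.26 from the other.

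Skeletal muscle and mast cell genes were the lists called, and the calls held only with the preset correlation between genes. Of 51 skeletal muscle genes 40 lay above 0, with a median log2 difference of 0.28 (limma camera adjusted p = 0.0199 with the preset correlation, and adjusted p = 0.988 with an estimated correlation). Ryr1, the calcium release channel of muscle, gave 0.64, and the sarcomere proteins Neb, Lmod2 and Mybpc2 gave 0.81, 0.69 and 0.72. Of 11 mast cell genes 10 lay above 0, with a median of 0.45 (adjusted p = 0.0199, and adjusted p = 0.988 with an estimated correlation). The mast cell proteases Cpa3, Cma1 and Mcpt4 gave 0.73, 0.61 and 0.45, and the receptor gene Mrgprb1 gave 0.83. No member of either list passed alone, neither over all genes nor adjusted over the list alone. Skeletal muscle list means did not separate the groups, since transgenic 11 stood at 10.85 and wildtype 26 at 11.28, and the same held for mast cells, with transgenic 11 at 8.44 and wildtype 26 at 8.82.

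The skeletal muscle call was lost without wildtype 29 (camera adjusted p = 0.837), where the list mean fell from 0.24 to 0.05. It was also lost without transgenic 7 (0.0861), without transgenic 17 (0.0546), without transgenic 7 and 84 (0.154, mean 0.11) and after cyclic loess normalization (0.0728). With the Gapdh ratio as a covariate the skeletal muscle mean turned to -0.09 (adjusted p = 0.12). The mast cell call was lost without transgenic 17 (adjusted p = 0.149), without wildtype 28 (0.159) and with the Gapdh ratio as a covariate (0.265). There the list mean fell from 0.485 to 0.28, 0.30 and 0.33. Over the alternatives the adjusted p ran from 1.97e-05 to 0.988 for skeletal muscle and from 0.00118 to 0.988 for mast cells. Of the 30 lists 2 were called, a number that was 1 without transgenic 17, 8 without wildtype 26 and 5 without wildtype 29, and 0 by the self-contained test fry, in which the smallest adjusted p was 0.292, for the circadian clock. Camera with an estimated correlation likewise called 0.

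**Figure D3:**
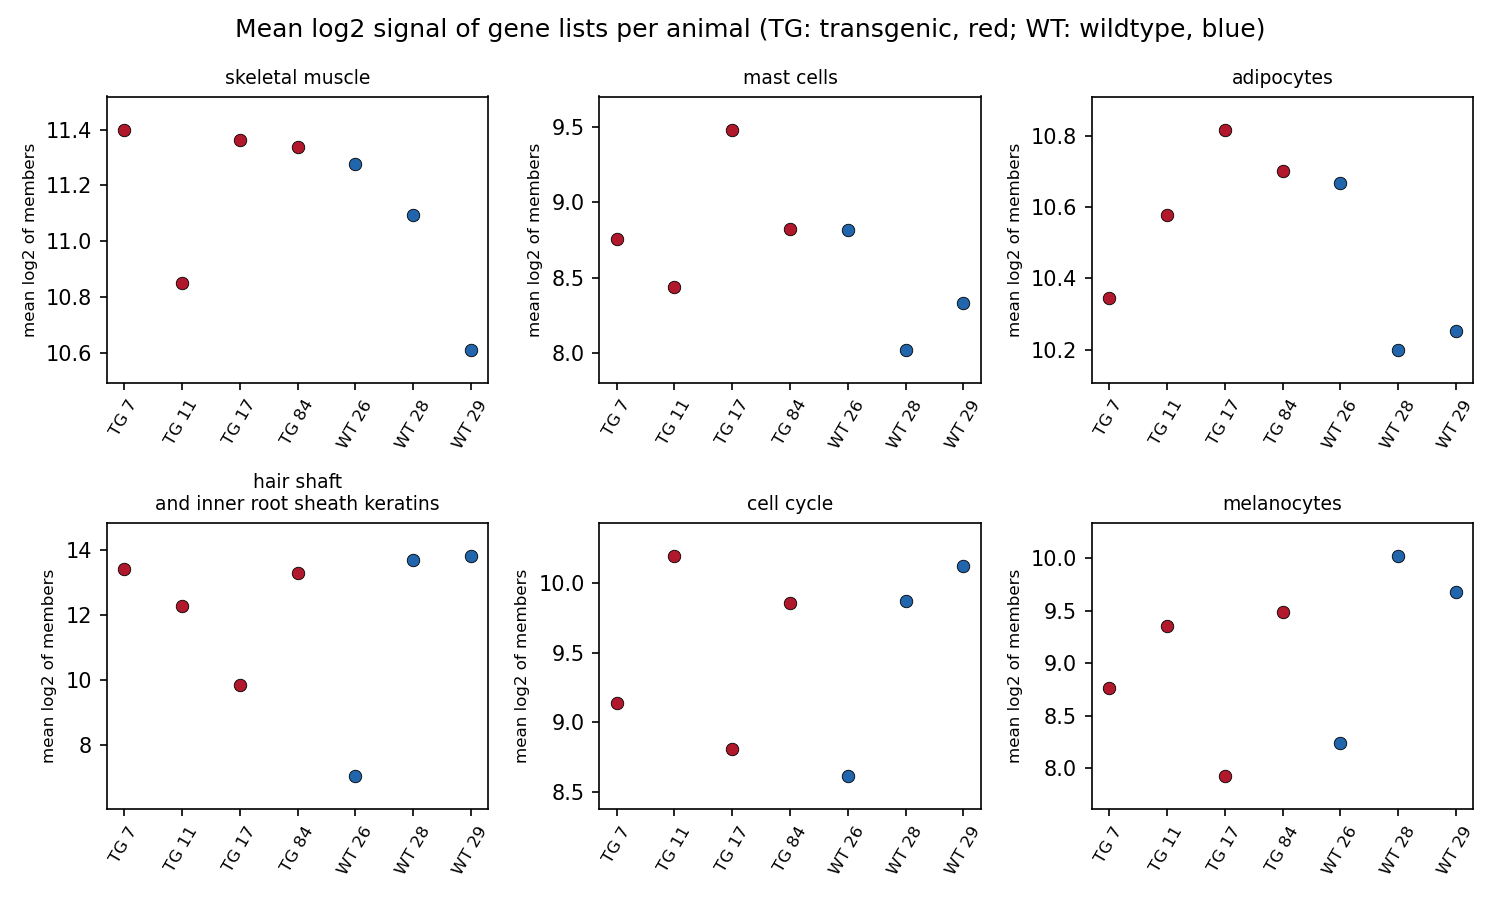
Mean log2 signal of the members of 6 gene lists in each of the 7 animals (transgenic red, wildtype blue). Skeletal muscle and mast cell means overlap between groups, with transgenic 11 at 10.85 and 8.44 and wildtype 26 at 11.28 and 8.82, and hair keratins are lowest in wildtype 26 at 7.04 and transgenic 17 at 9.84.

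Adipocyte genes lay higher without passing the list test. Of 26 genes 17 lay above 0, with a median log2 difference of 0.29 (adjusted p = 0.143). Lep passed when adjusted over the list alone, and Lpl, the lipoprotein lipase that takes up circulating lipid, measured 14.50 ± 0.18 in transgenic and 14.04 ± 0.08 in wildtype skin. Rbp4 and Pparg, the retinol carrier and the nuclear receptor of adipocyte differentiation, gave 0.95 and 0.57. The adipocyte list was called without transgenic 7 (adjusted p = 0.0168) and without wildtype 26 (0.0101), with a robust fit (0.0319), without transgenic 7 and 84 (0.0186) and with the hair keratin mean as a covariate (0.0217), all with the preset correlation (adjusted p = 0.988 with an estimated correlation over all 7 animals). Sebaceous gland and lipid synthesis genes had a median of 0.05 over 42 genes (adjusted p = 0.538), with Thrsp at 1.20 (other probe sets 0.15 and -0.34) and Dgat2 at 0.67 (the other -0.42). The sebaceous list was called without transgenic 7 and 84 (adjusted p = 0.0142) and with the Gapdh ratio as a covariate (0.00729), with medians of 0.21 and 0.32. Fibroblast and dermal matrix genes had a median of 0.05 and a mean of -0.02 over 41 genes (test direction up, adjusted p = 0.771), with 3 members higher and 2 lower at an unadjusted p under 0.05. Smooth muscle and pericyte genes had a median of -0.14 over 15 genes (adjusted p = 0.263; 0.0327 without wildtype 29 and 0.0462 with the mean over the probe sets of a gene). Endothelial genes had a median of -0.03 and a mean of 0.02 over 25 genes (test direction down, adjusted p = 0.864). Nerve and Schwann cell genes had a median of 0.05 over 16 genes (adjusted p = 0.971).

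Hair follicle genes varied more between animals than between groups. Keratins of the hair shaft and inner root sheath had a mean of 13.69 and 13.80 in wildtype 28 and 29 but 7.04 in wildtype 26. Transgenic 7, 84 and 11 stood at 13.41, 13.27 and 12.27, and transgenic 17 at 9.84. The list had a median log2 difference of 0.83 over 58 genes (adjusted p = 0.538), which turned to -1.59 without wildtype 26 (adjusted p = 5.1e-13) and was 1.61 without transgenic 17 (0.017), 2.02 without wildtype 28 (5.38e-05) and 2.06 without wildtype 29 (3.77e-05). Tchh, the hair protein trichohyalin, gave 1.12 and -0.43 without wildtype 26, and Krt75 gave -1.11. Hair follicle regulator and stem cell genes had a median of -0.06 over 48 genes (adjusted p = 0.266; 0.000184 without wildtype 26, 0.0207 without transgenic 7 and 84 and 0.00296 with the hair keratin mean as a covariate), with Hr at -0.45 and Sox9 at -0.65. Cell cycle genes had a median of -0.05 over 44 genes (adjusted p = 0.557; 1.71e-06 without wildtype 26 and 0.0459 with the hair keratin mean as a covariate). Melanocyte genes had a median of -0.56 over 13 genes (adjusted p = 0.263; 0.00118 without wildtype 26, 0.0303 without transgenic 7 and 84 and 0.00705 with the hair keratin mean as a covariate), with the pigment genes Mlana and Slc45a2 at -0.87 and -0.74. These p values rest on the preset correlation of 0.01 between genes, while the estimated correlation over all 7 animals was 0.977 for hair keratins, 0.866 for cell cycle, 0.472 for melanocyte and 0.235 for follicle regulator genes (adjusted p = 0.988 with an estimated correlation for each). The alternative fits were not repeated with an estimated correlation, here or for the other lists, and over all 7 animals the adjusted p with an estimated correlation was 0.988 for each of the 30 lists.

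Lists of the other immune cells gave no call. Macrophage genes had a median of 0.10 over 32 genes (adjusted p = 0.771; 0.000447 without wildtype 26), with 2 members higher and 2 lower at an unadjusted p under 0.05. T and natural killer cell genes had a median of 0.03 and a mean of 0.02 over 16 genes (test direction down, adjusted p = 0.971). B cell and plasma cell genes had a median of -0.08 and a mean of 0.07 over 10 genes (adjusted p = 0.971). Ighm, the heavy chain of immunoglobulin M, gave 1.42 and passed when adjusted over the list alone (adjusted p over all genes 0.301, and 0.0428 with the hair keratin mean as a covariate), while its other probe sets ran from -0.65 to 1.16. Neutrophil genes had a median of 0.34 over 11 genes (adjusted p = 0.413; 0.0303 without transgenic 7 and 84). Genes of Langerhans and dendritic cells with MHC class II had a median of -0.05 over 25 genes (adjusted p = 0.624). Interferon response genes had a median of -0.10 over 46 genes (adjusted p = 0.491; 0.00244 without wildtype 28), and H2-K1 passed when adjusted over the list alone. Blood genes had a median of -0.10 over 5 genes (adjusted p = 0.528).

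Signalling and housekeeping lists gave no call either. Junb, a subunit of the AP-1 transcription factor, measured 7.57 ± 0.32 in transgenic and 9.17 ± 0.56 in wildtype skin (log2 difference -1.60, adjusted p = 0.217) and passed when adjusted over the list alone in both lists that hold it. Wnt pathway and skin tumour growth signals had a median of 0.04 and a mean of -0.06 over 53 genes (test direction down, adjusted p = 0.557). Wnt10b lay below the level filter, at 5.39 ± 0.40 and 5.94 ± 0.54, and was not tested. Immediate early and heat shock genes had a median of 0.05 and a mean of -0.01 over 33 genes (test direction down, adjusted p = 0.624), and it was called lower with the Gapdh ratio as a covariate (median -0.12, adjusted p = 0.00295). At an unadjusted p under 0.05, 2 of its members lay higher and 4 lower. Lysosome and autophagy genes had a median of -0.05 over 45 genes (adjusted p = 0.266; 0.0378 without wildtype 29). Circadian clock genes had a median of 0.17 over 18 genes (adjusted p = 0.516). Mammary gland genes had a median of 0.40 and a mean of 0.13 over 13 genes (test direction down, adjusted p = 0.864), with the tight junction gene Cldn4 at -1.30 passing when adjusted over the list alone, and 1 member higher and 2 lower at an unadjusted p under 0.05. Cldn4 stood at 8.82 in transgenic 11, 8.38 in transgenic 17, 7.99 in transgenic 84 and 7.42 in transgenic 7. Its log2 difference ran from -1.52 to -0.49 over the alternatives. The mammary gland list was called lower with the Gapdh ratio as a covariate (median -0.49, adjusted p = 0.00365) and without transgenic 7 and 84 (-0.29, 0.0207). Epithelial secretory and sweat gland genes had a median of 0.47 over 9 genes, 8 of them above 0 (adjusted p = 0.263).

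The mixed sexes of both groups allowed a test of whether the transgene difference depended on sex. No gene passed it. Gbp2b, a guanylate-binding protein of the interferon response, had the smallest adjusted p at 0.72, with 6.23 and 6.24 in wildtype males 26 and 28, 9.36 in wildtype female 29, 9.86 and 10.46 in transgenic males and 9.33 and 9.16 in transgenic females. Limma called 0 probe sets for the interaction of group and sex, with 772 at an unadjusted p under 0.05 where 1351 would be expected. The wildtype group held 1 female, and the transgenic females were the animals with the highest Gapdh 3' to 5' ratios, 13.8 and 17.2.

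Sex-linked transcripts matched the sex given for all 8 arrays. Xist, the RNA of the inactive X chromosome, lay between 12.77 and 13.16 in females and between 6.81 and 7.10 in males. The Y-linked gene Eif2s3y lay between 11.32 and 11.44 in males and at or below 5.52 in females, and Uty at or above 8.92 in males and at or below 5.64 in females.

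The repeated array of wildtype female 29 gave the technical spread against which animals were compared. Over the tested probe sets the log2 difference between the 2 arrays of this animal had an SD of 0.401. The median SD between arrays of different animals was 0.696, which was 1.74 times as large. Whether the 2 arrays of wildtype 29 shared the labelling reaction or the RNA alone is not given in the sources used here, so 0.401 covers whichever steps were repeated. The median SD was 0.675 within the transgenic group, 0.741 within the wildtype group and 0.726 between groups. Within wildtype the pairs with wildtype 26 gave 0.741 to 0.840. Those of wildtype 28 with the arrays of wildtype 29 gave 0.461 and 0.453, so the wildtype median rested on wildtype 26. No test was made, as there was 1 technical pair. Without a level filter the ratio was 1.36 and with a filter at the 60th percentile it was 2.40.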

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

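All tests in this part were chosen after the results were seen.

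Of the 35 ways to split the 7 animals 4 against 3, 6, the real split included, called at least as many probe sets as the real one, which called 4, so chance cannot be excluded for that count. The highest count of another split was 863, with transgenic 11 placed beside the 3 wildtype animals against transgenic 7, 17 and 84, which follows the order of the Gapdh 3' to 5' ratio and points to a structure of the samples. The split into males and females called 56. For gene lists, 35 of 35 splits called at least the 2 of the real one, with 21 as the highest of the others, so chance cannot be excluded for the list calls either.

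More probe sets lay lower than higher in transgenic skin, 620 against 199 at an unadjusted p under 0.01 (75.7% lower), and 375 against 81 of these at 2-fold or more. The excess was small without wildtype 26, with 578 lower and 531 higher (52.1% lower), and by a test with no variance shared between probe sets, with 245 and 199 (55.2%). Lower and higher counts were 334 and 142 without transgenic 7, 1559 and 347 without transgenic 11, 462 and 153 without transgenic 17, 311 and 124 without transgenic 84, 182 and 76 without wildtype 28, and 244 and 118 without wildtype 29. The 3' to 5' log2 ratios of Gapdh (mean 2.67) and of the spike-ins (mean 2.32) in transgenic samples stood above those of wildtype in control probe sets that no comparison used. Probe sets picked as lower without transgenic 11 and wildtype 29 had a median difference between these held-out animals of -0.18, against -1.37 and -1.38 when transgenic 7 and 84 were held out in the same way (a ratio of 0.134), so labelling shortened towards the 3' end may account for part of the excess. The lower share was still 66.3% with the Gapdh ratio as a covariate (108 lower and 55 higher) and 68.4% without transgenic 7 and 84 (160 and 74). For genes with a probe set at least 2-fold lower at an unadjusted p under 0.01, the other probe sets fell less in the median. These 615 probe sets of 271 genes had a median of -0.07, or 0.052 of the picked ones, although both probe sets of Cap1 lay low. The ratio was as low for genes picked as higher (0.084 over 30 genes), so it is not particular to the lower ones. The same picking between the 2 animals lowest in hair keratins and the other 5 gave 0.501 for lower and 0.653 for higher genes, so the ratio can be high where animals differ. But the picked probe set was the one with the smallest p of its gene, which favours a low ratio whatever the cause. What picking alone gives was not tested, so the ratio cannot decide on a fall in mRNA of the genes picked as lower. For the 4 called probe sets shortened labelling stays open. Transgenic 11, with a wildtype-like ratio, had at least 0.721 of the shift of transgenic 7 and 84, but the fit that called them included this animal and favours probe sets in which all 4 transgenic animals are alike. With the ratio as a covariate none of the 4 passed the limma threshold (adjusted p from 0.306 to 0.79; 851 probe sets at an unadjusted p under 0.05), as the SE grew and some differences shrank. Gna13 went from -1.85 (SE 0.196) to -1.40 (SE 0.216), Khdrbs1 from 2.31 (SE 0.181) to 1.92 (SE 0.209), Rbm39 from -2.28 (SE 0.197) to -2.25 (SE 0.301), and the probe set without a symbol from 3.54 (SE 0.256) to 3.49 (SE 0.396). A weaker effect of the transgene in transgenic 11 stays open, because no annotated probe set measured the transgene.

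Neighbouring genes stood apart together, such as Trim12a, Trim30d and Trim34a, or Ang and Rpgrip1, and probe sets of the same gene often differed in shift, H2-D1 included. If the groups carried different strain backgrounds, sequence differences under the probes might produce both. Of 13536 tested genes with a known place, the 623 apart at an unadjusted p under 0.01 formed 336 pairs within 10 genes of each other, above the median of 283 and the 95% limit of 310 of 10000 random draws (share 0.0009). But 3 other splits of the animals reached as many as 336, with 348, 364 and 452. There genes were taken by rank, a rule that also gave 336 in the real split. The 452 came from transgenic 7 and 84 placed beside wildtype 28 and 29, the animals with the highest hair keratin means (13.27 to 13.80). The largest differences of that split included the hair genes Krtap19-4, Krtap19-9b and Krtap31-1. How many of its 452 pairs came from hair genes was not tested. As first stated, before the pairs were counted, the test took as many pairs in another split as evidence against strain differences, and by that bound they would be argued against. The bound was dropped after the count, because pairs in other splits show only that neighbours also stand apart together along other divisions of the animals. They therefore neither single out strain differences between the groups nor forbid them. The strain is not given in the sources used here, and strain differences and shared regulation of neighbours cannot be told apart.

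Hair shaft keratins were low in wildtype 26 (7.04) and transgenic 17 (9.84), across the groups. Shortened labelling is argued against, since the Gapdh ratio of wildtype 26 was 1.145 and transgenic 7 and 84, with ratios of 13.8 and 17.2, had keratin means of 13.41 and 13.27. A resting phase of the hair follicles in these animals may account for it, since 3 of 3 lists that should fall with it (cell cycle, melanocytes and hair follicle regulators) had the same 2 animals lowest. Wildtype 26 and transgenic 17 also stood highest in macrophage (11.25 and 11.04), T and natural killer cell (8.67 and 8.45) and endothelial genes (9.45 and 9.24). The shift was thus not limited to hair-related genes, and what a resting phase does to these other lists was not tested. The design gives no biological group that separates these animals, and hair cycle phase was not recorded in the sources used here.

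In 6 of 99 sets of 4 transgenic values, the highest or lowest animal lay far from the other 3, where about 5 would do so by chance. Rpgrip1 stood at 9.08 in transgenic 84, Tmem87a at 7.53 in transgenic 7 and Krt75 at 8.87 in transgenic 17. The cornified envelope list had a mean of 11.08 in transgenic 11, hair follicle regulators a mean of 8.78 in transgenic 17, and skeletal muscle a mean of 10.85 in transgenic 11.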

How the results depend on the processing

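The fits without transgenic 7 and 84 together and those with the Gapdh ratio or the hair keratin mean as a covariate were chosen after the results were seen. Of 1592 recomputed values of single genes and called lists, 1520 kept direction and side of the threshold, 37 lost and 26 gained a call, and 9 reversed. Only the 4 called probe sets and 2 called lists could lose a call, so most kept values were uncalled ones that stayed uncalled. Gna13 lost its call in 11 of 23 settings, Rbm39 in 6 of 23, Khdrbs1 in 4 of 23 and the probe set without a symbol in 4 of 22. The number of probe sets called, 4, was 10 with 4 times the pseudocount, 2 with a filter at the 60th percentile, 11 with sex as a covariate, 9 with the second array of wildtype 29, 28 with 8 arrays as separate samples, 14 at an adjusted p under 0.10, and 29 with the hair keratin mean as a covariate. It was 0 with the Gapdh ratio as a covariate (851 at an unadjusted p under 0.05), with 1 probe set per gene (1220 of 13559) and with no variance shared between probe sets (2454). Leaving out animals in turn gave 0 to 280. The number of lists called, 2, was 4 with quantile normalization and with the mean over probe sets of a gene, 7 without transgenic 7 and 84, 5 with the Gapdh ratio, 6 with the hair keratin mean, 0 with an estimated correlation and 0 with fry, and 1 to 8 with animals left out. The interaction count stayed at 0 in each fit made (492 to 1729 probe sets at an unadjusted p under 0.05, smallest adjusted p 0.0706), and could not be fitted without wildtype 29, the only wildtype female. The spread ratio of 1.74 was 1.36 without a filter and 2.40 at the 60th percentile. Reversals were the skeletal muscle mean with the Gapdh ratio (-0.094), Ctsd with that covariate (0.006), Ctsb after cyclic loess (-0.071), without transgenic 7 and 84 (-0.024) and with the Gapdh ratio (-0.17), and, with animals left out, Ctsl (-0.165 to 0.04), Ctsb (-0.018 to 0.174) and Tchh (-0.43 to 1.92). The normalizations moved the median log2 difference by at most 0.04. Treating the animal as a random block was not run, since 8 arrays in 7 blocks gave a correlation estimate for 0 probe sets. No paired analysis was possible because the animal numbers are not shared between groups. Detection calls were not given, so background was judged from signal level alone.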

Other observations

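All values in this part were chosen after the results were seen.

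Genes of the proliferating and pigmented hair follicle moved together across animals regardless of group. Cell cycle genes had list means of 8.61 in wildtype 26 and 8.81 in transgenic 17, and between 9.14 and 10.19 in the other 5 animals. Melanocyte genes stood at 8.24 and 7.93 in these animals and between 8.77 and 10.02 in the others. Hair follicle regulators stood at 8.87 and 8.78, against 9.64 to 9.997. Among the other 5 animals the lists did not keep the same order. Transgenic 11 had the highest cell cycle mean (10.19) but the lowest hair keratin mean of these (12.27). Transgenic 7 had the lowest cell cycle (9.14) and melanocyte (8.77) means of these, with hair keratins at 13.41.

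Genes that stood apart between the groups at an unadjusted p under 0.01 formed 23 stretches of at least 4 neighbours on assembly GRCm38.p6. Trim12a, Trim30d and Trim34a lay in a stretch of 5 with Trim21 and Trim5. Cap1 lay in a stretch of 8 with Zmpste24, Smap2, Rlf, Nfyc, Mycl, Rhbdl2 and Hivep3. Ang and Rpgrip1 lay in a stretch of 4 with Mettl17 and Supt16, Tmem87a in a stretch of 4 with Rpap1, Vps39 and Haus2, and Rbm39 in a stretch of 5 with Nfs1, Scand1, Epb41l1 and Dlgap4.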
